A study of Mus musculus with 18 samples.

How the data were processed

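What was measured is messenger RNA per gene in about 500 sorted CD4+ effector T cells per library. Per the labels, cDNA was made with the Clontech SMART-Seq v4 ultra low input kit and turned into libraries with the NEBNext Ultra II DNA kit, a chemistry that keeps no strand of origin in its usual form. The deposited values used here are estimated counts per gene, as the file headers name them, 1 column per library and not all whole numbers. The submitters' processing notes list Salmon, DESeq2 and the genome build mm10, with no versions and no roles. The annotation behind the counts was not given in the sources used here. The 18 count columns were used, and 37 other columns with abundance, length and import settings were not. The values held counts, so the plan for counts was followed in place of the one for TPM that had been put first.

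The table held 34162 mouse Ensembl gene identifiers. Of these, 34083 matched a symbol and a position in the GENCODE vM21 annotation of GRCm38 (mm10), and 79 matched none. Columns are named by organ and by CD45.1 positive or negative, and the negative ones were taken as CAR-deficient by elimination. The columns carry no replicate numbers. The 3 libraries of each group are therefore called a, b and c in column order, which is a name and no claim about shared hosts or days.

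Counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the 6 groups, which left 14876. Library sizes were scaled by TMM, dispersions were estimated with estimateDisp (common biological coefficient of variation 0.791), and 6 group means were fitted to all 18 libraries with glmQLFit (robust off). Each of 10 comparisons was tested two-sided with glmQLFTest, and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05 and no fold threshold. The comparisons were CAR-deficient minus wild type in each organ and averaged over the 3 organs, organ against organ in wild type cells, and the differences of the genotype effect between organs. The standard error beside a log2 fold change is the absolute log2 fold change over the square root of the F statistic. Levels are CPM on TMM-scaled library sizes (edgeR's cpm), as mean ± SD with n = 3 libraries per group. The p-values measure the spread between these libraries alone, since nothing in the labels says that the libraries of a group came from separate animals. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

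A total of 33 gene lists covered T cell states, nuclear receptor biology, stress, metabolism, markers of other cell types and the chromosome 1 neighbourhoods of 2 genes. Of these, 32 had at least 3 tested members and were tested with limma's camera on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the lists of a comparison. Each test was repeated with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone. Single values fixed in advance, and list means, were also tested by exact permutation of genotype within organ (8000 assignments), the single values on log2(CPM + 1), which does not keep column endings together. Within 1 organ, 3 libraries against 3 allow no p under 0.1.

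Genes were named by this rule. The first part is Nr1i3. The second takes, in each comparison, the 10 largest absolute log2 fold changes per direction among genes past the threshold, without overlap between the libraries of the compared groups and with a mean of at least 5 CPM in 1 compared group. For the average over organs the same sign in each organ replaced the overlap condition, and the differences of the genotype effect had none. Where fewer than 3 genes passed in a direction, the 3 with the smallest p under the same level condition were added, named as not past the threshold. The third takes, from each list in the genotype comparisons and the organ comparisons of wild type cells, up to 4 members past the threshold, or at most 2 with the smallest p. The fourth is Abcb1a, Abcb1b, Cyp2b10, Il10, Ifng, Tnf, Il17a, Foxp3, Ccr9, Itgae and Ptprc in every case. Gene models without a name and receptor or immunoglobulin variable segments were counted and not named one by one, and the text shortens the longest sets. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The exceptions are the organ comparisons in CAR-deficient cells and the alternatives said to be added later.

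Total counts ran from 19605135 to 25436389 per library. A floor of 3 counts corresponded to 0.108 to 0.185 CPM. Shares of receptor counts carry 95% exact Clopper-Pearson intervals. The reads are PCR copies without molecular identifiers, so intervals and floors cover counting error only.

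The pipeline was tested on simulated data with the group sizes and spread of these libraries and 50 changed genes per fold. For 1 organ's genotype comparison it recovered 0%, 22%, 40% and 40% of changes of 2, 4, 8 and 16 fold, with 1 false call. For the average over organs it recovered 22%, 40%, 74% and 76%, with 6 false calls. For siLP against spleen it recovered 0%, 24%, 44% and 54%, with 3 false calls, and for the difference of the genotype effect between siLP and spleen 0%, 6%, 14% and 42%, with 0 false calls. Of simulated lists, 3 of 5 shifted by 1.5 fold and 5 of 5 shifted by 2 fold were called, and 0 of 15 without a shift. Simulated genes varied independently, without the shared deviations of libraries with the same column ending. These list counts therefore say nothing about false calls in lists whose genes vary together.

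The alternatives were no filter, a stricter filter (5 CPM in 3 libraries), DESeq2 size factors, library totals without further scaling, limma's voomWithQualityWeights, DESeq2's Wald test, a fit of the compared groups alone, no chromosome 1 genes, and leaving out each library in turn. The column ending as a batch term, voomWithQualityWeights with that term, and fits without the 6 libraries named a, without receptor and immunoglobulin segments or without the wild type libraries a and b were added after seeing the data. So was an exact permutation that swaps genotype only between libraries of an organ with the same column ending (512 assignments). It counts the pairs of different organs as independent, as do the fits averaged over organs, which the labels do not establish.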

Results

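Messenger RNA was sequenced from about 500 sorted CD4+ effector T cells per library, 3 weeks after T cells had been transferred into Rag-deficient mice, which make no T or B cells of their own. The transferred cells were either wild type and marked by CD45.1, a variant of the leukocyte surface protein encoded by Ptprc, or lacked CAR, the nuclear receptor encoded by Nr1i3 that senses foreign compounds and drives drug-handling genes. Cells came from the spleen, the lamina propria of the colon (cLP) and the lamina propria of the small intestine (siLP). The 6 groups hold 3 libraries each, 18 in all. Total estimated counts per library ran from 19605135 to 25436389, and 15466 to 18819 genes had counts. The T cell marker genes Cd4 and Cd8a were looked up after the data had been seen. Cd4 lay between 109 and 236 CPM in every library, and Cd8a reached at most 2.44 CPM.

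In each group the library called a stood apart from b and c. The 6 a libraries had 15466 to 16128 genes detected, against 17013 to 18819 in the other 12. Mitochondrial genes took 3.70% to 3.98% of their counts against 2.23% to 3.22%, and the 50 highest genes 25.3% to 29.0% against 20.1% to 24.5%. The first principal component, with 23.2% of the variance, placed them at 45.5 to 151 and the others at -86.6 to 9.02. Each group holds 1 of them. Deviations from the group mean were correlated above 0.1 in 41 of 45 pairs of libraries with the same column ending and in 7 of 90 other pairs.

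Nr1i3 (ENSMUSG00000005677, chr1:171213970-171220701, plus strand) had fewer than 3 counts, a floor of 0.108 to 0.185 CPM, in 10 of the 18 libraries and counts in both genotypes. Wild type libraries a, b and c held 36, 0 and 7 counts in spleen, 0, 0 and 10 in cLP and 0, 5 and 0 in siLP. CAR-deficient libraries held 0, 14 and 14 in spleen, 0, 29 and 1 in cLP and 196, 0 and 0 in siLP. The siLP CAR-deficient library a thus had 9.49 CPM, the highest level of the 18, and without it the mean of that group was 0 (n = 2). In this column the pseudogene Gm28438, named after its values were seen, read 40.8 CPM. CAR-deficient libraries had 28.5 to 78.6 CPM of it and wild type ones at most 5.27 CPM. Trbv26, a receptor beta V segment also named after its values were seen, held 0% of its beta V counts. In siLP wild type a it held 68.5%, and in wild type libraries c at most 0.727%. These values argue against a swap with siLP wild type a. Whether the CAR-deficient label is otherwise right stays open, which bears on every siLP and averaged genotype value. The log2 fold change of Nr1i3 averaged over organs was 2.21 ± 1.45 (edgeR, adjusted p = 0.978). It became -0.85 when siLP CAR-deficient library a was left out. Exact permutation gave p = 1 in siLP, 0.7 in cLP, 1 in spleen and 0.437 over the organs. Within an organ 0.1 is the smallest possible p. A gene-level count does not separate deleted from remaining exons. Tomm40l, a gene of a mitochondrial import subunit that overlaps Nr1i3 on the opposite strand, had 14.9 ± 5.86 CPM in wild type and 1.77 ± 1.37 CPM in CAR-deficient siLP cells (average log2 fold change -1.61 ± 0.51, adjusted p = 0.525), and reads from the overlap cannot be assigned to a strand.

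Averaged over the 3 organs, the genotype comparison asks what differs between CAR-deficient and wild type effector cells wherever they reside. The wild type cells also carry the congenic marker CD45.1, so a difference is not by itself an effect of CAR. Btg2 (ENSMUSG00000020423, chr1:134075170-134079120), an antiproliferative gene, rose in CAR-deficient cells with a log2 fold change of 1.66 ± 0.19 (9 libraries per genotype). It went from 45.9 ± 14.7 to 137 ± 43.6 CPM in spleen, from 128 ± 8.39 to 415 ± 108 in cLP and from 145 ± 37.8 to 473 ± 153 in siLP (n = 3 each), and each CAR-deficient library lay above each wild type library of its organ. The test was edgeR with Benjamini-Hochberg adjustment, which gave adjusted p = 0.00362. Cd55b (ENSMUSG00000026401, chr1:130388537-130423009), which encodes a complement decay-accelerating factor, was named after its values were seen because it lies under 5 CPM. It fell from mean levels of 0.775, 0.729 and 1.10 CPM in wild type spleen, cLP and siLP to 0, 0.0164 and 0 CPM (adjusted p = 0.0386). Both genes lie on chromosome 1 within 10 Mb of Ptprc, the congenic marker gene. These 2 of 14876 genes passed, 859 had an unadjusted p under 0.05 where 744 are the chance number, and voomWithQualityWeights called 11 and DESeq2's Wald test 123. Leaving out a library kept Btg2 in all 18 fits (log2 fold change 1.55 to 1.74) and Cd55b in none. The fits without 1 library called 3 genes without siLP wild type c, 2 without siLP wild type a or siLP CAR-deficient c, and 1 without each other library. With the column ending as a batch term, added after the results had been seen, 7 genes passed. Leaving out the 6 wild type libraries a and b, so that library c was the only wild type library of each organ, gave Btg2 a log2 fold change of 1.61.

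Cell cycle genes were lower as a list in CAR-deficient cells, with 20 of 22 members below 0, 0 members past the threshold over all genes and 0 adjusted over the list alone. Examples are Tyms, which makes thymidylate (-0.61 ± 0.19), and Ube2c, a ubiquitin ligase component of mitosis (-0.65 ± 0.19, adjusted p = 0.464). Camera gave adjusted p = 2.93e-06, and adjusted p = 0.502 with an estimated correlation. Cytotoxic genes were higher as a list (12 of 17 above 0, adjusted p = 0.00494; adjusted p = 0.183 with an estimated correlation). Here 0 members passed over all genes and 5 adjusted over the list alone: Gzma, Klrg1, Klrd1 and Klre1 higher and Gzmk lower, the full set named after its values were seen. Gzma, a granule protease, had a log2 fold change of 2.76 ± 0.47 (adjusted p = 0.113), which with the column ending as a batch term (Gzma, genotype average) became 2.88 and passed (adjusted p = 0.0349), and Klre1, a killer cell lectin-like receptor, 2.76 ± 0.64 (adjusted p = 0.241). Th1 genes, the interferon gamma helper programme, were higher (15 of 18, adjusted p = 0.00946; adjusted p = 0.311 with an estimated correlation), with Il18rap at 1.39 ± 0.30 and Ly6c2 at 0.77 ± 0.22 past when adjusted over the list alone and 0 over all genes. Its call ended without siLP wild type b (adjusted p = 0.0693) or siLP CAR-deficient a (0.0767). Exact permutation of genotype within organ, which does not keep column endings together, left none of the lists past the threshold after adjustment over the lists (cell cycle adjusted p = 0.552, cytotoxic adjusted p = 0.464). Neither did exact permutation within organ and column ending, added after the results had been seen (cell cycle and Th1 adjusted p = 0.0833, cytotoxic adjusted p = 0.172). The smallest p that this permutation allows is 0.0039, so a list reaching it alone could not pass over 32 lists. Th1 genes reached it, higher in 9 of 9 pairs. Cell cycle genes were lower in 8 of 9 pairs (permutation p = 0.0078) and cytotoxic genes higher in 7 of 9 (permutation p = 0.043). Of markers of other cells, the intestinal epithelial list was higher (12 of 13 above 0, adjusted p = 0.0141; adjusted p = 0.394 with an estimated correlation), a call that ended without cLP CAR-deficient b (0.0738). Those of CD8, NK and innate lymphoid cells (adjusted p = 0.850), of macrophages, monocytes and neutrophils (0.896) and of erythroid cells (0.773) did not pass. The genes beside Nr1i3 (adjusted p = 0.850) and beside Ptprc (0.492) did not pass as lists either.

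IL-10 and coinhibitory receptor genes were lower as a list in CAR-deficient cells (adjusted p = 0.0273; adjusted p = 0.619 with an estimated correlation), with 0 members past over all genes and 3 adjusted over the list alone, Il10, Icos and Lag3, named after their values were seen. Il10 (ENSMUSG00000016529, chr1:131019845-131024974), which encodes an anti-inflammatory cytokine, read 417, 237 and 90.9 CPM in wild type and 76.9, 47.3 and 21.5 CPM in CAR-deficient cLP. In siLP it read 574, 251 and 33.7 CPM in wild type and 148, 87.5 and 83.1 CPM in CAR-deficient cells, where the genotypes overlap. Its averaged log2 fold change was -1.78 ± 0.56 (adjusted p = 0.525). It was 0.57 without the wild type libraries a and b, where the list (IL-10 and coinhibitory receptor genes, genotype average) turned upward. That fit sets wild type c alone against CAR-deficient a, b and c. In cLP and siLP, Il10 fell from a to c in both genotypes. Paired by organ and column ending, Il10 was lower in CAR-deficient cells in 8 of 9 pairs, and so was the list. In the 6 wild type libraries a and b Trbv26, a receptor beta V segment named after its values were seen, held most beta V counts. Il10 also lies within 10 Mb of Ptprc. Lag3, an inhibitory receptor, had -1.71 ± 0.53 (adjusted p = 0.511). Treg genes were lower as a list (12 of 16 below 0, adjusted p = 0.0290; adjusted p = 0.183 with an estimated correlation), as were cholesterol synthesis and efflux genes (17 of 20, adjusted p = 0.0424; adjusted p = 0.763 with an estimated correlation). Gut homing and tissue residency genes were higher (14 of 19, adjusted p = 0.0424; adjusted p = 0.394 with an estimated correlation), with 0 members past in any of the 3 lists. Leaving out 1 library ended the Treg call in 6 of 18 fits (up to 0.0713 without cLP CAR-deficient b), the IL-10 list call in 10 (up to 0.251 without spleen CAR-deficient c), and the cholesterol and gut homing calls in 13 each (up to 0.151 without cLP wild type b and 0.138 without cLP CAR-deficient c).

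**Figure D1:**
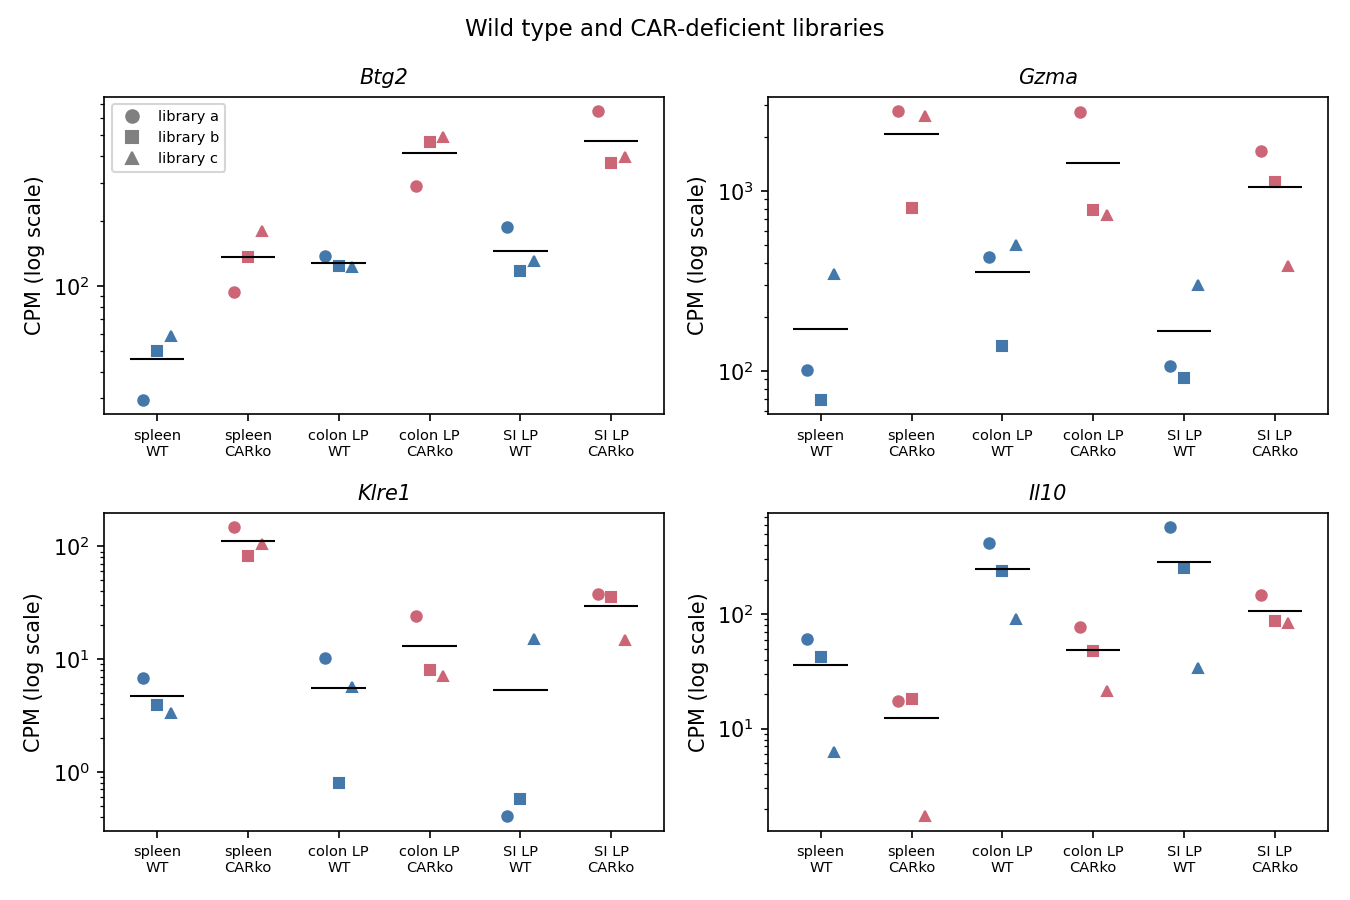
CPM on a log axis of Btg2, Gzma, Klre1 and Il10 in wild type (blue) and CAR-deficient (red) libraries of spleen, cLP and siLP, with circle, square and triangle for libraries a, b and c and a line at each group mean of 3. CAR-deficient Btg2 runs from 93.2 CPM in spleen to 650 CPM in siLP, above every wild type library of the same organ.

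The averaged change of the CAR and PXR target and drug handling list, the genes the receptor is known to drive in liver, did not pass (adjusted p = 0.654), nor did it in siLP (adjusted p = 0.497), with 0 of 21 tested members past the threshold. Abcb1a, the multidrug efflux pump MDR1, had 33.6 ± 17.3 CPM in wild type and 56.9 ± 21.2 CPM in CAR-deficient siLP cells (log2 fold change 0.76 ± 0.48, average 0.39 ± 0.28, adjusted p = 0.992). Its paralog Abcb1b averaged 0.19 ± 0.23 (adjusted p = 1.00). Cyp2b10, the classical CAR target in liver, stayed at or below a group mean of 0.0493 CPM and was not tested by edgeR (exact permutation p = 1). The glutathione transferases Gsta4 and Gstm1 had averaged values of -3.15 ± 1.43 and -2.52 ± 1.27 (adjusted p = 0.856 and 0.889). Among effector genes, Ifng averaged 0.53 ± 0.36 (adjusted p = 0.986), Tnf 0.20 ± 0.27 (adjusted p = 1.00) and Il17a -4.19 ± 1.76 (adjusted p = 0.805). Paired by organ and column ending, Il17a was lower in CAR-deficient cells in 5 of 9 pairs and higher in 0. The remaining pairs showed no difference. Foxp3, the regulatory T cell factor, averaged -1.02 ± 1.58 (adjusted p = 1.00), the gut homing receptor Ccr9 -1.06 ± 0.61 (adjusted p = 0.935) and the integrin Itgae 0.88 ± 0.63 (adjusted p = 0.995). Ptprc averaged 0.42 ± 0.16 (adjusted p = 0.726). Exact permutation within organ gave p = 0.0385 for Il10, 0.0413 for Itgae and 0.0158 for Ptprc, each 0.165 after Benjamini-Hochberg adjustment over the 12 genes fixed in advance. Permuted within organ and column ending, an exact test added after the results had been seen, Il10, Ifng and Ptprc passed (adjusted p = 0.0469 each) and Itgae did not (adjusted p = 0.15). This test counts its 9 pairs as independent. Libraries with the same column ending correlated above 0.1 across groups in 41 of 45 pairs, so these p-values may be too small. Other genes with small p in the average were Odc1, the first enzyme of polyamine synthesis (-1.57 ± 0.31, adjusted p = 0.152), and Hist1h4n, a histone H4 gene (1.53 ± 0.29, adjusted p = 0.152), neither past the threshold. With the column ending as a batch term (Hist1h4n, genotype average) the latter had 1.48 and passed (adjusted p = 0.0349).

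In siLP, the wall of the organ that takes bile acids back up, cell cycle genes were lower as a list in CAR-deficient cells (19 of 22 below 0, 0 past over all genes and 0 adjusted over the list alone). Mcm2, a replication licensing factor, had -1.09 ± 0.43 and Ube2c -0.90 ± 0.34. Camera gave adjusted p = 0.000550, and adjusted p = 0.774 with an estimated correlation. Th1 genes were higher as a list (17 of 18 above 0, adjusted p = 0.0419; adjusted p = 0.768 with an estimated correlation), with Ly6c2 at 0.98 ± 0.38 and Il18rap at 1.19 ± 0.52. The genes with the smallest p, none past the threshold (adjusted p = 1), were Btg2 (1.70 ± 0.34), Dennd5a (1.28 ± 0.29; 15.9 against 38.7 CPM) and Cops8, a signalosome subunit (-1.32 ± 0.32; 80.0 against 32.0 CPM), and Haao, of tryptophan breakdown, had 5.82 CPM in wild type and 0 in CAR-deficient cells. By edgeR 0 genes passed and 641 had an unadjusted p under 0.05, below the 744 expected by chance. By voomWithQualityWeights 2 passed and by DESeq2's Wald test 35 (9 higher, 26 lower). The cell cycle call ended without siLP wild type b (adjusted p = 0.488) or CAR-deficient a (0.410), and the Th1 call without wild type b (0.488), wild type c (0.120) or CAR-deficient a (0.606).

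In cLP, cell cycle genes were again lower as a list in CAR-deficient cells (20 of 22 below 0, adjusted p = 2.23e-06; adjusted p = 1.00 with an estimated correlation), with Tyms at -1.09 ± 0.33 and Ube2c at -0.84 ± 0.34 and 0 members past the threshold over all genes. Intestinal epithelial cell markers were higher (10 of 13 above 0, adjusted p = 0.00356; adjusted p = 0.903 with an estimated correlation), with the immunoglobulin transporter Pigr at 4.39 ± 1.60 and the lectin Lgals4 at 2.70 ± 1.05. That call ended without cLP CAR-deficient b (adjusted p = 0.139), in which the epithelial adhesion gene Epcam, named after its values were seen, read 29.1 CPM against 0 and 5.95 in the other CAR-deficient libraries. With the column ending as a batch term, added after the results had been seen, 2 further lists were lower by camera with the preset correlation. They were Th17 genes (adjusted p = 0.0261, 0.143 without the term) and IL-10 and coinhibitory receptor genes (0.0208, 0.125 without it). The genes with the smallest p were Btg2 (1.70 ± 0.34), Hist1h4n (2.08 ± 0.52), Tmem45b (0.254 against 7.47 CPM) and Hmgn1, a nucleosome-binding protein (-1.20 ± 0.31; 85.6 against 37.3 CPM), none past the threshold (adjusted p = 1). By edgeR 0 genes passed and 363 had an unadjusted p under 0.05, below the 744 expected by chance. By voomWithQualityWeights 3 passed and by DESeq2's Wald test 12.

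In spleen, cytotoxic genes were higher as a list in CAR-deficient cells, with 15 of 17 members above 0. Gzma read 102, 69.2 and 345 CPM in wild type and 2792, 804 and 2629 CPM in CAR-deficient libraries (log2 fold change 3.59 ± 0.84). Klre1 had 4.68 ± 1.84 CPM in wild type and 112 ± 33.7 CPM in CAR-deficient cells (4.58 ± 1.20), and Klrg1, a marker of terminal effector cells, 121 ± 55.3 and 382 ± 165 CPM (1.66 ± 0.38, n = 3 per group). Camera gave adjusted p = 1.71e-08, and adjusted p = 0.00469 with an estimated correlation. Over all genes 0 of the 17 passed (adjusted p = 1 for Gzma), and Gzma, Klrg1 and Klre1 passed adjusted over the list alone. The markers of CD8, NK and innate lymphoid cells, which share Gzma with this list, did not pass (adjusted p = 0.319). Other lists passed by camera with the preset correlation once the column ending was a batch term, added after the results had been seen. Th1 genes were then higher (adjusted p = 0.00701). Th17 genes and Treg genes (adjusted p = 0.00211 each) and IL-10 and coinhibitory receptor genes (0.0284) were lower. None of these lists passed without the term, where Th17 and Treg genes came nearest (adjusted p = 0.0579 each). Of the genes with the smallest p, Ifi211, an interferon-inducible gene of a family with close paralogs, had -2.34 ± 0.70 (72.1 against 14.2 CPM), and Tox2, a transcription factor, -1.84 ± 0.57 (48.5 against 13.5 CPM), neither past the threshold (adjusted p = 1). Ifi211 lies at 173.9 Mb of chromosome 1, within 10 Mb of Nr1i3, and is not particular to spleen. Its log2 fold change averaged over organs was -2.00 ± 0.40 (edgeR, adjusted p = 0.152). By edgeR 0 genes passed and 290 had an unadjusted p under 0.05, below the 744 expected by chance. By voomWithQualityWeights 5 passed. By DESeq2's Wald test 17 did, among them Gzma, Klre1, Klrg1 and Klra4, another killer cell lectin-like receptor, named after its values were seen.

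**Figure D2:**
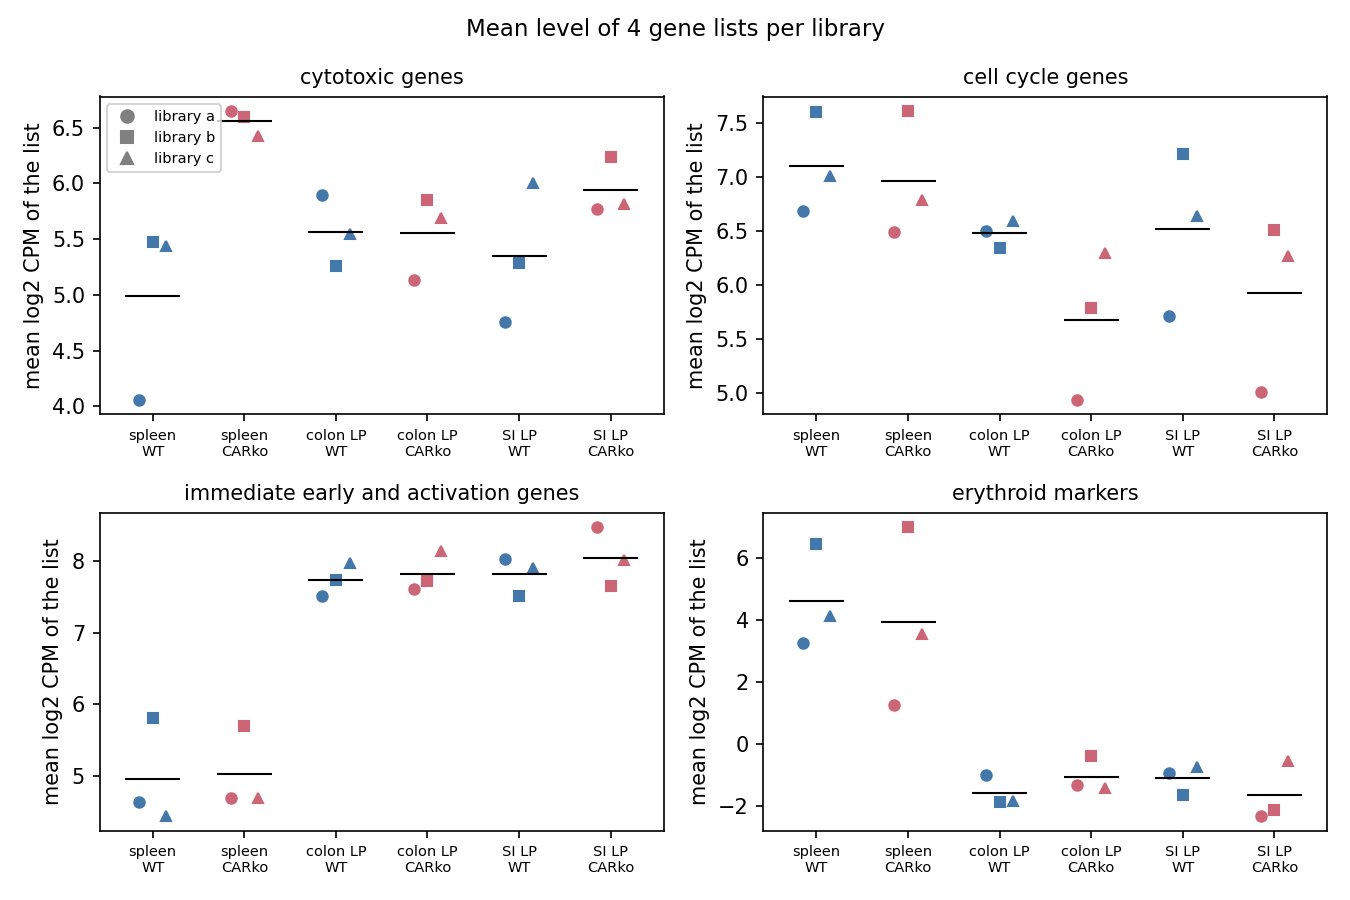
Mean log2 CPM over the members of 4 gene lists (cytotoxic, cell cycle, immediate early and activation, erythroid) in each of the 18 libraries, wild type in blue and CAR-deficient in red, with circle, square and triangle for libraries a, b and c and lines at group means. Cytotoxic scores were 4.06, 5.48 and 5.44 in wild type and 6.65, 6.60 and 6.43 in CAR-deficient spleen.

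Whether the genotype difference itself differed between organs was tested by its interaction with organ. Cytotoxic genes differed more between genotypes in spleen than in cLP (adjusted p = 5.70e-05; adjusted p = 0.0397 with an estimated correlation) and more than in siLP (adjusted p = 0.0372; adjusted p = 0.649 with an estimated correlation). Cell cycle genes were lower in CAR-deficient cells of cLP relative to spleen (adjusted p = 0.000857; adjusted p = 0.973 with an estimated correlation) and of siLP relative to spleen (adjusted p = 0.0372; adjusted p = 0.955 with an estimated correlation). Epithelial markers were higher in cLP relative to spleen (adjusted p = 0.00635; adjusted p = 0.621 with an estimated correlation). No gene passed by edgeR in any of the 3 interactions. Unadjusted p-values under 0.05 numbered 337 (siLP against spleen), 184 (cLP against spleen) and 358 (siLP against cLP), each below the 744 expected by chance. By voomWithQualityWeights 0 genes passed in each, and by DESeq2's Wald test 12, 8 and 14. The siLP against spleen calls ended in 8 of 12 fits without 1 library for cytotoxic genes (up to 0.246 without siLP wild type c) and in 7 of 12 for cell cycle genes (up to 0.586 without siLP CAR-deficient a). In cLP against spleen the cell cycle call ended without spleen CAR-deficient b (0.223) and the epithelial call without cLP CAR-deficient b (0.0600).

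Comparing siLP with spleen in wild type cells asks what distinguishes effector cells in the gut wall. Immediate early and activation genes rose, with 20 of 20 tested members above 0, 5 past the threshold over all genes and 19 adjusted over the list alone. Nr4a1 (ENSMUSG00000023034, chr15:101254269-101274795), an orphan nuclear receptor induced by antigen receptor signals, went from 3.48 ± 2.33 to 180 ± 52.1 CPM (log2 fold change 5.69 ± 0.68, adjusted p = 0.00177). Tnfaip3 (ENSMUSG00000019850, chr10:19000910-19015657), a brake on NF-kB signalling, went from 79.5 ± 15.4 to 683 ± 314 CPM (3.10 ± 0.36, adjusted p = 0.00177). The AP-1 gene Fosb had 3.93 ± 0.57, the stress factor Atf3 6.56 ± 1.23 (5.98 to 12.13 without 1 library) and Cd69, an early activation and residency marker, 2.99 ± 0.52 (299 to 2372 CPM). Other genes that rose were Rgs2, a regulator of G protein signalling (3.98 ± 0.73), the transcription factors Klf4 (3.29 ± 0.57) and Tgif1 (3.00 ± 0.50), Dennd4a (3.07 ± 0.43), Lsmem1 (6.58 ± 1.22) and the inhibitory receptor Ctla4 (2.67 ± 0.51). Camera gave adjusted p = 4.55e-43 for the immediate early list, and adjusted p = 0.00326 with an estimated correlation.

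Heat shock genes rose with them in siLP (12 of 12 above 0, adjusted p = 4.14e-11; adjusted p = 0.0398 with an estimated correlation), with 2 members past over all genes and 6 adjusted over the list alone. The chaperone genes Hspa1b (2.50 ± 0.46, adjusted p = 0.0417) and Dnajb1 (2.06 ± 0.39, adjusted p = 0.0483) are those 2. Erythroid markers were lower as a list (7 of 7 below 0, adjusted p = 4.84e-13; adjusted p = 0.0163 with an estimated correlation), 0 past over all genes and 4 adjusted over the list alone. The haemoglobin gene Hba-a2, whose reads its paralog Hba-a1 shares, had 687 ± 493 CPM in spleen and 1.76 ± 1.51 CPM in siLP (adjusted p = 0.0627). The list of IL-10 and coinhibitory receptor genes was also higher (adjusted p = 0.0154; adjusted p = 0.498 with an estimated correlation), as were the nuclear receptors and bile acid receptors (adjusted p = 0.0164; adjusted p = 0.530 with an estimated correlation), and cell cycle genes were lower (adjusted p = 0.00112; adjusted p = 0.585 with an estimated correlation). Stromal and endothelial markers were higher (adjusted p = 0.0154; adjusted p = 0.534 with an estimated correlation), with the matrix gene Dcn at 257, 7.04 and 3.05 CPM in the 3 libraries, a call that ended without siLP wild type a (0.224). Mitochondrial genome genes were lower as a list (13 of 13 below 0, adjusted p = 0.0154; adjusted p = 0.667 with an estimated correlation), a call that ended in 3 of 6 fits without 1 library (up to 0.493 without spleen wild type a). The genes fixed in advance had values of 2.39 ± 0.49 for Tnf (adjusted p = 0.0773), 2.27 ± 0.65 for Ifng (adjusted p = 0.471), 2.98 ± 1.01 for Il10 (adjusted p = 0.798) and 2.48 ± 1.09 for Ccr9 (adjusted p = 1.00), none past the threshold. With the column ending as a batch term Il10 (2.84, adjusted p = 0.0414), Ifng (2.11, adjusted p = 0.00863) and Hba-a2 (-8.50, adjusted p = 0.0314) passed. By edgeR 676 genes had an unadjusted p under 0.05, below the 744 expected by chance, and in all 28 rose and 0 fell past the threshold. The count was 3 without spleen wild type a or c, 7 without siLP wild type c, 10 without siLP wild type a, 15 without spleen wild type b or siLP wild type b, and 0 in a fit of these 2 groups alone. Nr4a1 and Tnfaip3 passed in all 6 fits without 1 library, Fosb and Dennd4a in 4, Atf3, Cd69, Rgs2, Klf4, Tgif1, Ctla4 and Hspa1b in 1, and Lsmem1 and Dnajb1 in 0. The list calls of immediate early, heat shock and erythroid genes held in all 6. The calls of IL-10, nuclear receptor and cell cycle lists ended in 3, 3 and 2 of them (up to 0.331 without spleen wild type c, 0.121 without spleen wild type a and 0.0599 without spleen wild type b).

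**Figure D3:**
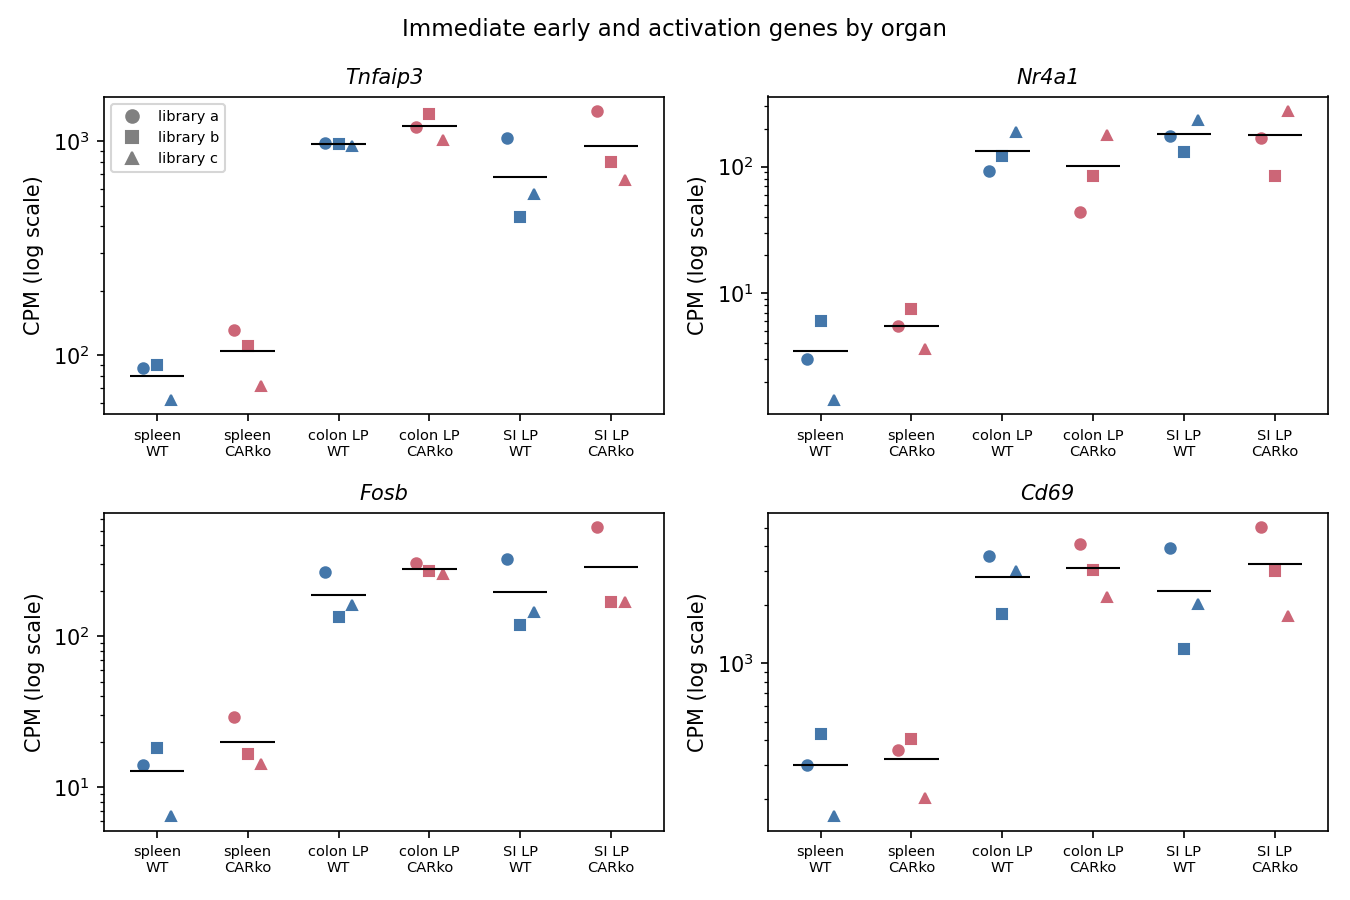
CPM on a log axis of Tnfaip3, Nr4a1, Fosb and Cd69 in wild type (blue) and CAR-deficient (red) libraries of spleen, cLP and siLP, with circle, square and triangle for libraries a, b and c and a line at each group mean of 3. Mean Nr4a1 was 3.48 CPM in wild type spleen, 134 in cLP and 180 in siLP.

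In cLP against spleen, wild type cells had the same gene group higher. Nr4a1 rose to 134 ± 49.8 CPM (log2 fold change 5.26 ± 0.67, adjusted p = 0.00140) and Tnfaip3 to 968 ± 19.4 CPM (3.60 ± 0.37, adjusted p = 0.000358). Of the 20 tested immediate early and activation genes, 20 were above 0, 8 passed over all genes and 18 adjusted over the list alone (adjusted p = 6.48e-32; adjusted p = 0.0121 with an estimated correlation). Other genes that rose include Klf4 (4.41 ± 0.60), Rgs2 (4.41 ± 0.75), the AP-1 gene Fosl2 (5.36 ± 0.95), the stress-induced Nupr1 (7.01 ± 1.29), Rgcc (4.13 ± 0.72), Nr4a3 (4.06 ± 0.81), Ctla4 (3.23 ± 0.53), Cd69 (3.22 ± 0.53), Ccno (6.51 ± 1.32) and the heat shock gene Dnajb1 (2.34 ± 0.40). Heat shock genes were higher as a list (adjusted p = 8.24e-10; adjusted p = 0.0604 with an estimated correlation). The stromal and endothelial marker Sparc, a matrix protein, rose from 0.0703 ± 0.0454 to 63.0 ± 63.5 CPM. It was 1 member past over all genes and 8 adjusted over the list alone of the stromal and endothelial markers, which were higher as a list (adjusted p = 1.84e-06; adjusted p = 0.171 with an estimated correlation). Dcn of that list read 0.169, 565 and 921 CPM in the 3 wild type cLP libraries. Intestinal epithelial markers were higher (adjusted p = 0.000860; adjusted p = 0.171 with an estimated correlation).

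The gene that fell in cLP was Hbb-bt, a beta haemoglobin, from 112 ± 80.4 CPM in spleen to 0 in cLP (adjusted p = 0.0399). Erythroid markers were lower as a list (adjusted p = 3.91e-12; adjusted p = 0.0215 with an estimated correlation). Cell cycle genes were lower (adjusted p = 0.000168; adjusted p = 0.439 with an estimated correlation), and unfolded protein and integrated stress response genes were higher (adjusted p = 0.000767; adjusted p = 0.288 with an estimated correlation). Th17 genes were higher (adjusted p = 0.0307; adjusted p = 0.288 with an estimated correlation), a call that ended without cLP wild type c (adjusted p = 0.191). By edgeR 55 genes rose and 1 fell, with 1132 at an unadjusted p under 0.05 (744 by chance), while voomWithQualityWeights called 789. The count was 13 without spleen wild type a, 14 without spleen wild type c, 36 without spleen wild type b, 34 without cLP wild type b, 11 in a fit of the 2 groups alone and 144 with the column ending as a batch term. Nr4a1, Tnfaip3 and Klf4 passed in all 6 fits without 1 library, Rgs2 in 5, Ctla4 and Cd69 in 4, Fosl2 and Rgcc in 3, Nupr1 and Dnajb1 in 2, Sparc and Nr4a3 in 1, and Ccno and Hbb-bt in 0.

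Between siLP and cLP in wild type cells, no gene passed. Epithelial markers were lower in siLP as a list (adjusted p = 0.00520; adjusted p = 0.818 with an estimated correlation), with 0 members past over all genes and 7 adjusted over the list alone, among them Krt19, a keratin (0 in siLP, 2.50 CPM in cLP). Stromal and endothelial markers were lower as well (adjusted p = 0.0126; adjusted p = 0.954 with an estimated correlation). Of the genes with the smallest p, Lmna, a nuclear lamin, had -3.11 ± 0.67 (6.26 against 54.2 CPM), Tm2d2 -1.49 ± 0.34, Hist1h4n 1.90 ± 0.52, Plekhg2 1.54 ± 0.44 and the gut homing integrin Itga4 0.89 ± 0.26 (adjusted p = 1 for each). By edgeR 0 genes passed and 639 had an unadjusted p under 0.05, below the 744 expected by chance. By voomWithQualityWeights 93 passed and by DESeq2's Wald test 28. The epithelial call ended without siLP wild type c (adjusted p = 0.107), and the stromal call in 4 of 6 fits without 1 library (up to 0.495 without cLP wild type c).

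T cell receptor beta V counts were dominated by Trbv26 in wild type libraries a and b of each organ. Its share of beta V counts there was 72.0% and 57.8% in spleen, 67.3% and 57.0% in cLP and 68.5% and 52.0% in siLP, with the widest 95% Clopper-Pearson interval at 56.0% to 58.0% for cLP b. Wild type libraries c had 0.227% in spleen, 0.727% in cLP and 0.281% in siLP. In CAR-deficient libraries a, b and c the shares were 0%, 0.466% and 0.404% in spleen, 0%, 0.258% and 0.301% in cLP and 0%, 0.478% and 0.0478% in siLP. The counts of 0 allow shares of up to 0.0413%, 0.0412% and 0.0237% in the 3 organs. These values were looked up after the data had been seen, and reads of V segments with close paralogs are assigned with less certainty.

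**Figure D4:**
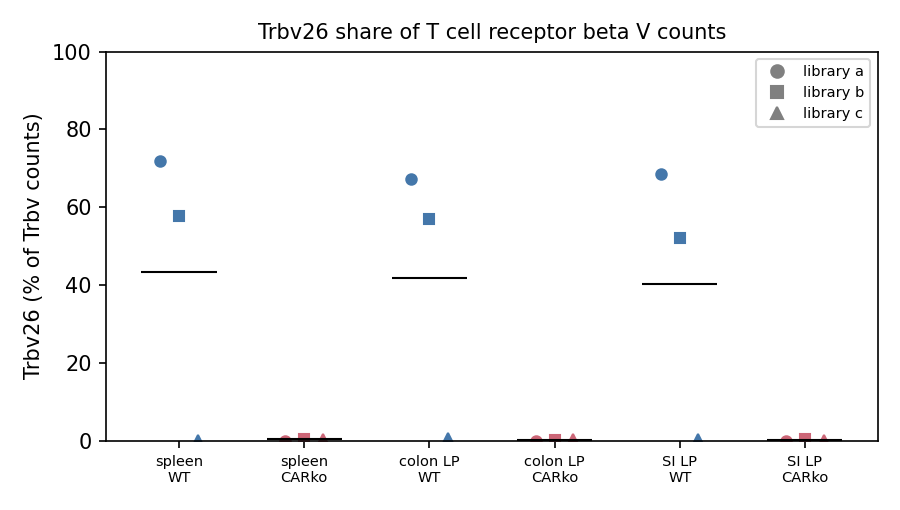
Trbv26 as a percentage of all T cell receptor beta V counts (linear axis) in each library of the 6 groups, wild type in blue and CAR-deficient in red, with circle, square and triangle for libraries a, b and c and a black line at the mean of 3. The 6 wild type libraries a and b lie between 52.0% and 72.0% and the other 12 at or under 0.727%.

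**Figure D5:**
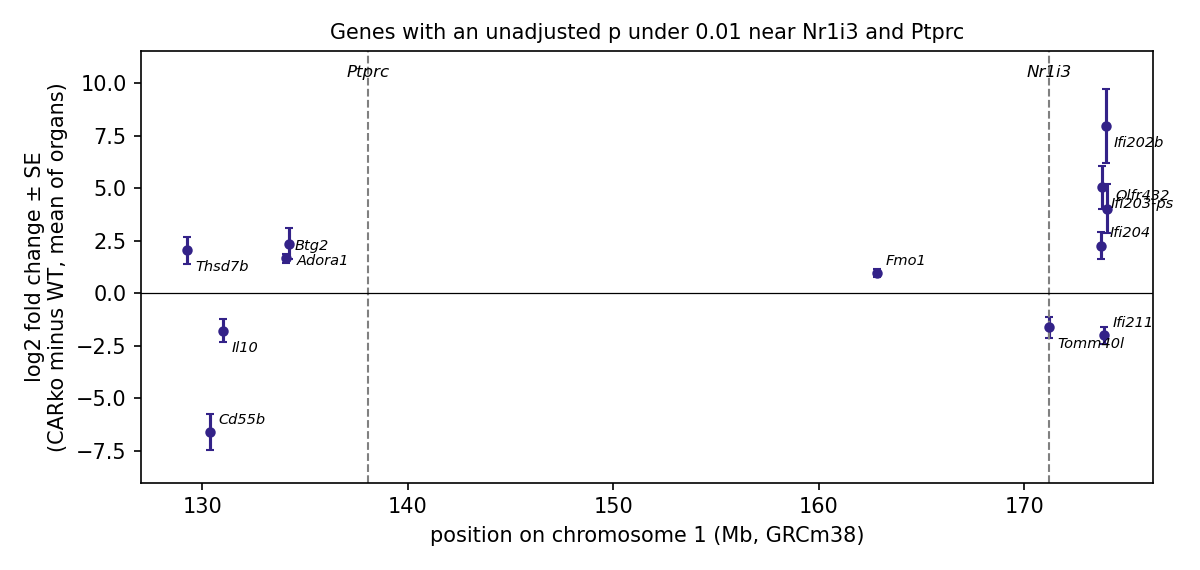
Log2 fold change ± SE of CAR-deficient minus wild type cells, averaged over organs, for the 12 genes with an unadjusted p under 0.01 within 10 Mb of Nr1i3 or Ptprc, by position on chromosome 1 in Mb (GRCm38), with dashed lines at both genes. Btg2 lies at 134 Mb with 1.66 ± 0.19, and the value of Cd55b, at 0 in most CAR-deficient libraries, depends on the prior count.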

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

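All tests in this part, including the splits, were chosen before the results had been seen, except the reading of which libraries a split parts. By camera with the preset correlation, the genotype difference itself differed between organs in 5 pairings of a gene list with an organ contrast. Cytotoxic and cell cycle genes are each counted for cLP and for siLP against spleen. Cytotoxic genes were raised in CAR-deficient cells of spleen more than of cLP (adjusted p = 5.70e-05; adjusted p = 0.0397 with an estimated correlation). They were also raised more in spleen than in siLP (adjusted p = 0.0372; adjusted p = 0.649 with an estimated correlation). Cell cycle genes were lower in CAR-deficient cells of cLP relative to spleen (adjusted p = 8.57e-04; adjusted p = 0.973 with an estimated correlation). In siLP relative to spleen they were lower too (adjusted p = 0.0372; adjusted p = 0.955 with an estimated correlation). Intestinal epithelial cell markers were higher in CAR-deficient cells of cLP relative to spleen (adjusted p = 0.00635; adjusted p = 0.621 with an estimated correlation), and 0.0600 without cLP CAR-deficient b.

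For single genes the 3 interactions called 0, so all 100 of the 100 splits drawn necessarily gave as many, and these splits say nothing about chance. The highest other count was 0 for siLP against spleen, 622 for cLP against spleen and 0 for siLP against cLP. The split with 622 genes placed the a libraries of cLP on one side and those of spleen on the other, which points to a structure of the samples by column ending. No biological explanation was tested for these 5 differences.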

How the results depend on the processing

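The column ending as a batch term (alone or with voomWithQualityWeights), and the fits without the 6 libraries named a, without receptor segments or without the wild type libraries a and b, and the exact permutation within column endings, were chosen only after the results had been seen. With 3 libraries per group and a common biological coefficient of variation of 0.791, changes of 2 fold within an organ were recovered in 0% of simulated genes. No paired analysis was possible by replicate number, because the columns carry none, so the planned block by that number could not be fitted. Libraries were instead paired by column ending, in a batch term and in an exact permutation of 9 pairs, as a hint from the data. Libraries with the same ending correlated above 0.1 in 41 of 45 pairs. The rule set in advance, written for replicate numbers, asked for this in every pair between the compared groups. Each pair that missed it held siLP CAR-deficient b (0.0230 to 0.0695). Comparisons without siLP CAR-deficient cells thus met it by column ending, while the main counts stayed unpaired. The pseudocount for TPM was not run, since counts were used. Of the 43 list calls, 43 kept direction and call with DESeq2 size factors and 43 with the column ending, 36 with voomWithQualityWeights, 40 with library totals (3 lost) and 39 without a filter (4 lost), with none reversed. No gene direction reversed among these either. Of the 64 named genes compared, 62, 59, 51, 56 and 57 kept their side of the threshold under the same settings. Of the 43 list calls, 28 kept and 15 lost their call without the 6 libraries named a, and 40 kept and 3 lost it in fits of the groups of the contrast alone. Of the 64 genes, 52 kept their side, 9 lost and 3 gained the call without the libraries a, and 35 kept and 29 lost it in fits of the groups alone. Without chromosome 1 genes 8 of 13 list calls were kept and 5 lost, with 11 of 11 genes the same. Without the wild type libraries a and b, library c is the only wild type library of each organ, so calls there are not compared. Of 8 lists 1 reversed direction in that fit, and of 5 genes 1 did. Library totals moved the median of all genes by over 0.1 in siLP against cLP alone (0.127, against -0.02 with TMM).

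Genotype siLP, genotype cLP and genotype spleen, 0 genes by edgeR: voomWithQualityWeights called 2, 3 and 5, the DESeq2 Wald test 35, 12 and 17, the fit without the 6 libraries named a 1, 2 and 1, and voomWithQualityWeights with the column ending 1, 1 and 1. Genotype average, 2 genes: 10 without a filter, 1 with the strict filter, 11 with voomWithQualityWeights, 123 with the DESeq2 Wald test, 7 with the column ending, and 5 with voomWithQualityWeights and that term. Without chromosome 1 genes it was 0, since both genes lie there. For siLP against spleen in WT, 28 genes became 18 with library totals, 105 with voomWithQualityWeights, 138 with the DESeq2 Wald test, 64 with the column ending and 45 with voomWithQualityWeights and that term. For cLP against spleen in WT, 56 genes became 789, 294, 144 and 223 under the last 4 of these, and 124 without the libraries a. Fitting the groups of the contrast alone, which leaves fewer samples to estimate the spread, gave 0 and 11. All 28 and all 56 genes were among those of voomWithQualityWeights, the Wald test and the column ending term. For siLP against cLP in WT, 0 genes became 93, 28 with the Wald test, and 18 without the libraries a. The interactions siLP against spleen, cLP against spleen and siLP against cLP gave 12, 8 and 14 genes with the Wald test. Gene list tests: 43 calls became 7 with an estimated correlation, and 71 with voomWithQualityWeights and the column ending. The column ending alone gave 55, with none of the 43 lost, and the added ones include Th17 genes, lower in the genotype average (adjusted p = 0.0238). For the other moved counts, these list calls included, the cause was not tested.

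Nr1i3 level: the averaged log2 fold change of 2.21 became -0.15 without the 6 libraries named a, which hold the 196 counts of siLP CAR-deficient a. Il10, genotype average, went from -1.78 to 0.57 without the wild type libraries a and b, and the IL-10 and coinhibitory receptor genes, genotype average, turned upward there (adjusted p = 0.394); the cause was not tested.

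Leaving out each library in turn gave -0.85 to 3.81 for the Nr1i3 level, 1 to 3 genes for genotype average, 3 to 15 for siLP against spleen in WT, 13 to 49 for cLP against spleen in WT and 0 to 0 for the other comparisons.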

Other observations

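All tests of explanations here were chosen only after the results had been seen, except the counts of other splits. Organ comparisons in CAR-deficient cells were added after seeing the data. In them 30 genes rose and 2 fell in siLP against spleen, and 69 rose and 3 fell in cLP against spleen. Immediate early and activation genes were higher as a list in siLP (adjusted p = 3.51e-38; adjusted p = 0.00559 with an estimated correlation) and in cLP (adjusted p = 3.39e-25; adjusted p = 0.0312 with an estimated correlation). Cell cycle genes were lower in siLP (adjusted p = 2.28e-09; adjusted p = 0.239 with an estimated correlation) and in cLP (adjusted p = 4.94e-11; adjusted p = 0.141 with an estimated correlation). Th17 genes were higher in siLP (adjusted p = 0.00646; adjusted p = 0.239 with an estimated correlation) and in cLP (adjusted p = 0.0354; adjusted p = 0.302 with an estimated correlation). Stromal and endothelial markers were higher in cLP (adjusted p = 1.90e-07; adjusted p = 0.0886 with an estimated correlation), as were epithelial markers (adjusted p = 2.89e-07; adjusted p = 0.0509 with an estimated correlation). Between siLP and cLP, 0 genes passed by edgeR, with 910 at an unadjusted p under 0.05.

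The unprocessed pseudogene Gm28438 (chr1:24612775-24613119), named after its values were seen, had 28.5 to 78.6 CPM in all 9 CAR-deficient libraries and 0 in all wild type libraries except 2.19 CPM in cLP a and 5.27 CPM in siLP a (averaged adjusted p = 0.132, and 0.0349 with the column ending as a batch term). In receptor use, Trbv16 held 56.3% of beta V counts in spleen CAR-deficient c.

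Trbv26 held 52.0% to 72.0% of beta V counts in wild type libraries a and b of each organ. A strain variant of the congenic background would raise it in every CD45.1 library, and the highest share in libraries c was 0.727%, which argues against it. An expanded clone may account for it, and 1 clone should give an alpha V family of at least 40% in each of these 6 libraries, but the top one, Trav7, held 26.2% to 46.8% and reached 40% in 2 of 6. Trav7 was also the top family in the CAR-deficient libraries a (31.9% to 33.5%), so the alpha V counts leave the clone open. A second beta V segment, Trbv23, held 6.12% to 16.9% in these 6 libraries and at most 0.196% in the others, and its link to Trbv26 was not tested.

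The 2 genes past the threshold in the averaged genotype comparison, Btg2 and Cd55b, lie on chromosome 1. Genes within 10 Mb of Nr1i3 or Ptprc had an unadjusted p under 0.01 in 12 of 270 cases against 199 of 14396 elsewhere, but genes among these 12 had prompted the test. With the genes named before left out on both sides it was 7 of 243 against 172 of 14175 (odds ratio 2.41, 95% interval 0.946 to 5.16, Fisher's exact p = 0.0321), and the interval reaches below 1. Among the 12, Ifi204, Ifi203-ps, Ifi211, Ifi202b and Olfr432 start between 173.747 and 174.049 Mb. Fisher's test counts such neighbours as independent, so its p may be too small and its interval too narrow. A strain variant near the targeted or the congenic gene may contribute, which these values leave open. An effect of CAR on these genes was not separated from the region by any test.

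Immediate early genes were higher in gut than in spleen libraries of both genotypes. Markers of epithelial, stromal or myeloid cells rose by at most 0.0582 of the rise of the immediate early genes in siLP (0.00116 to 0.0582 over 3 libraries) and by at most 0.128 in cLP (0.0464 to 0.128). How much immediate early RNA such cells bring per marker was not measured, so RNA of these cells is left open in both organs. Stress during enzymatic isolation of lamina propria cells may raise the same genes, and the list was higher in 4 of 4 gut against spleen comparisons. Isolation differs with the organ, so it cannot be told apart from a response of the cells in the gut.

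Other splits of the libraries were counted. For the genotype average, 1 of 100 splits, the real one, gave at least 2 genes, and the highest other gave 1. That is a small margin, since 15 of 18 fits without 1 library call 1 gene, and the splits did not keep the column endings together. In siLP against spleen (28 genes, highest other 0) and cLP against spleen (56 genes, highest other 0), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. In genotype siLP, genotype cLP, genotype spleen and siLP against cLP, the real split gave 0 genes, so 10 of 10 splits necessarily gave as many (highest other 0), and these splits say nothing about chance.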
